A study of Mus musculus with 8 samples.

How the data were processed

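Gene expression was measured by RNA sequencing in 8 libraries of sorted Lineage- Sca-1+ c-Kit+ (LSK) bone marrow cells from mice. Per the labels, RNA came from about 10000 sorted cells per extract, cDNA was made with SMART-Seq HT and libraries with Nextera XT. Per the submitters' processing notes, reads were handled with TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 1.0 and Cuffnorm 2.2.1 on the mm10 genome. The deposited values were FPKM (mapped fragments scaled by transcript length and library size), not log transformed, with 1 value per gene symbol and library. The unit was read from the values together with the naming of Cuffnorm, since the file headers do not state it. The gene annotation and Cuffnorm's library normalisation are not given in the sources used here. Of 23284 gene symbols, 20911 matched a reference set of current gene symbols. Gene positions on GRCm38 (mm10) were taken from GENCODE vM21.

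Fragment counts were not among the files used here, so depth is known only by estimate. The smallest step between values of 139 genes with a single transcript gave an approximate depth for the first glucose library, 7.41 in units of 1000000 fragments, with quartiles of 6.85 and 7.69 across those genes. The other libraries were scaled to it by the ratio of the value of 1 fragment, over 227 to 278 genes. No counting intervals were computed from these estimates.

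The 8 libraries fell into 4 groups of 2: glucose, glucose with lipid, and a pair of PBS groups. The series gives each treatment its respective PBS controls but does not say in words which they are. Sample letters H and I are shared by glucose with lipid and PBS replicates 1 and 2, and the column names of these 4 libraries carry a tag that the other 4 lack. PBS replicates 1 and 2 (H and I) were therefore taken as controls of glucose with lipid, and PBS replicates 3 and 4 (J and K) as controls of glucose. The glucose libraries carry letters A and B, which neither PBS pair shares, so their controls were assigned by elimination and by the missing tag. This assignment is an inference from names. Pearson correlations of glucose libraries ran from 0.9602 to 0.9653 with PBS replicates 1 and 2, and from 0.9490 to 0.9635 with PBS replicates 3 and 4. Likeness across genes thus did not favour PBS J and K as the controls of glucose.

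Values were transformed to log2(FPKM + 1), and the 11931 genes with at least 1 FPKM in at least 2 libraries were tested. Linear models with a mean-variance trend were fitted in limma 3.58.1 under R 4.3.3, with all 8 libraries in 1 fit, 4 residual degrees of freedom and 3.73 prior degrees of freedom. The comparisons were glucose against PBS J and K, glucose with lipid against PBS H and I, the difference of these effects, and PBS H and I against PBS J and K. P-values were 2-sided and adjusted by Benjamini-Hochberg at 0.05 over the genes of each comparison. A fit of all 4 treated against all 4 PBS libraries, with the control set as a block, was added after the values had been seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

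The comparisons, filters, gene lists and rule for naming genes were fixed before the data were examined. The 36 lists held 1010 memberships, 987 of them in the files, and covered stem and progenitor cell identity, ageing, energy and lipid metabolism, cell cycle, stress and immune responses, and markers of other marrow cell types. The 34 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists, with an estimated correlation and fry beside it. A list's median is the median log2 fold change of its tested members. Each treatment comparison named, per direction, the 8 genes with the largest log2 fold change among those that passed, had a mean of at least 3 FPKM and had both treated libraries beyond both controls. Places left over went to the genes with the smallest unadjusted p under the same separation and level rules, which did not pass. Up to 4 members of each list that passed camera, 5 genes per direction for the difference of effects, and 20 genes chosen from the study's subject were also named. Predicted genes, clones, microRNAs, small nucleolar RNAs, pseudogenes and receptor segments were counted but not named by the rule.

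The procedure was tested on simulated data with 200 changed genes in 10 simulations. Noise was drawn independently for each gene and library, with no difference between control sets. The changed genes were taken from those with a mean log2 value above 2, so recovery at lower levels was not measured. With 2 libraries against 2, it found 57.7% of genes changed by 1 on the log2 scale in the glucose comparison and 57.5% in the comparison with lipid. It found 94.0% and 95.6% of those changed by 2, with 8.7 and 7.7 false calls on average. The fit of 4 against 4 found 87.3% and 99.0%, with 11 false calls on average. A list shifted by 0.6 was found in 10 of 10 simulations in each comparison. Genes were uncorrelated there, so this does not show how lists fare when their members vary together.

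Alternatives covered pseudocounts of 0.1 and 0.5, no filter or a filter at 5 FPKM, quantile normalisation, median centring and no variance trend. They also covered only the 4 libraries of a comparison, pooled or crossed PBS controls, the replicate number as a block, under which only PBS replicates 1 and 2 serve as controls, and leaving out each library in turn. Where a left-out library leaves a group with 1 library, that library was assumed to vary like the other groups. Removal of microRNA and small nucleolar RNA values, library weights, and pooled controls with glucose with lipid reduced to replicate 2 were added after the data had been seen. To weigh depth, also after the data had been seen, each immediate early gene was set beside the 50 other genes nearest to it in mean log2 value over the PBS libraries. The lists of endothelial and of stroma and bone markers were not tested, having 4 tested members each.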

Results

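LSK cells, the marrow fraction that holds haematopoietic stem cells and multipotent progenitors, were profiled in C57BL/6 males aged 12 to 13 weeks. For 7 days, mice fasted for over 14 hours were given intravenous glucose (2 g/kg), glucose plus a 20% lipid emulsion (6 mL/kg), or phosphate-buffered saline (PBS), and marrow was taken on day 8. The series title places the question in how glucose and triglyceride after meals bear on transcription and ageing of marrow stem cells. There were 2 libraries of glucose, 2 of glucose with lipid and 4 of PBS, all labelled biological replicates. The labels do not say whether a library came from 1 mouse or a pool. Estimated depths, in units of 1000000 fragments, were 7.41 and 6.61 for glucose replicates 1 and 2, and 5.82 and 8.45 for glucose with lipid. For PBS replicates 1 to 4 they were 6.34, 6.26, 5.97 and 6.02. Between 11186 and 11771 genes reached 1 FPKM per library, and the microRNA gene Mir682 alone took 18.5% to 24.2% of the summed FPKM.

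The glucose comparison addresses what repeated glucose without lipid does to LSK transcripts. After glucose, 10 genes other than microRNAs rose in LSK cells, among them Nr4a1, Plk2 and Cdkn1a. Nr4a1, an orphan nuclear receptor induced within minutes of many stimuli, stood at 240.6 ± 90.0 FPKM (SD, n = 2) against 25.9 ± 1.63 in PBS J and K. Plk2, a polo-like kinase, stood at 63.9 ± 12.8 FPKM against 6.47 ± 1.68. Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 55.8 ± 1.95 FPKM against 18.1 ± 2.07, and it lay higher in all 4 treated than in all 4 PBS libraries.

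Among the genes other than microRNAs that passed, the largest log2 fold changes were those of Nr4a1 (3.12 ± 0.28 SE, adjusted p = 0.00699) and Plk2 (3.12 ± 0.22, adjusted p = 0.00234). Btg2, an antiproliferative gene, rose by 2.3 ± 0.26 (adjusted p = 0.0257), and Nfkbiz, an atypical IkB protein, by 2.18 ± 0.14 (adjusted p = 0.00182). Dusp5, a nuclear phosphatase of ERK, rose by 1.91 ± 0.14 (adjusted p = 0.00234), the kinase gene Sik1 by 1.70 ± 0.16 (adjusted p = 0.00699) and Cdkn1a by 1.58 ± 0.12 (adjusted p = 0.00234). The histone gene Hist1h2bc rose by 1.75 ± 0.19 (adjusted p = 0.0203), from 26.8 ± 5.96 to 92.5 ± 21.2 FPKM, but PBS H and I held 146.8 ± 9.48 FPKM, and with these as controls its change was -0.68. Named here after their values were seen, the early activation marker Cd69 rose by 1.53 ± 0.14 (adjusted p = 0.00699) and Ppp1r15a, which directs a phosphatase to eIF2alpha, by 1.32 ± 0.12 (adjusted p = 0.00699). On GRCm38, Nr4a1 lies on chromosome 15 at 101254269 to 101274795, Plk2 on chromosome 13 at 110395046 to 110400844, and Cdkn1a on chromosome 17 at 29090976 to 29100727. Dusp5 lies on chromosome 19 at 53529109 to 53542431, Nfkbiz on chromosome 16 at 55811375 to 55838899, and Sik1 on chromosome 17 at 31844250 to 31855804.

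**Figure D1:**
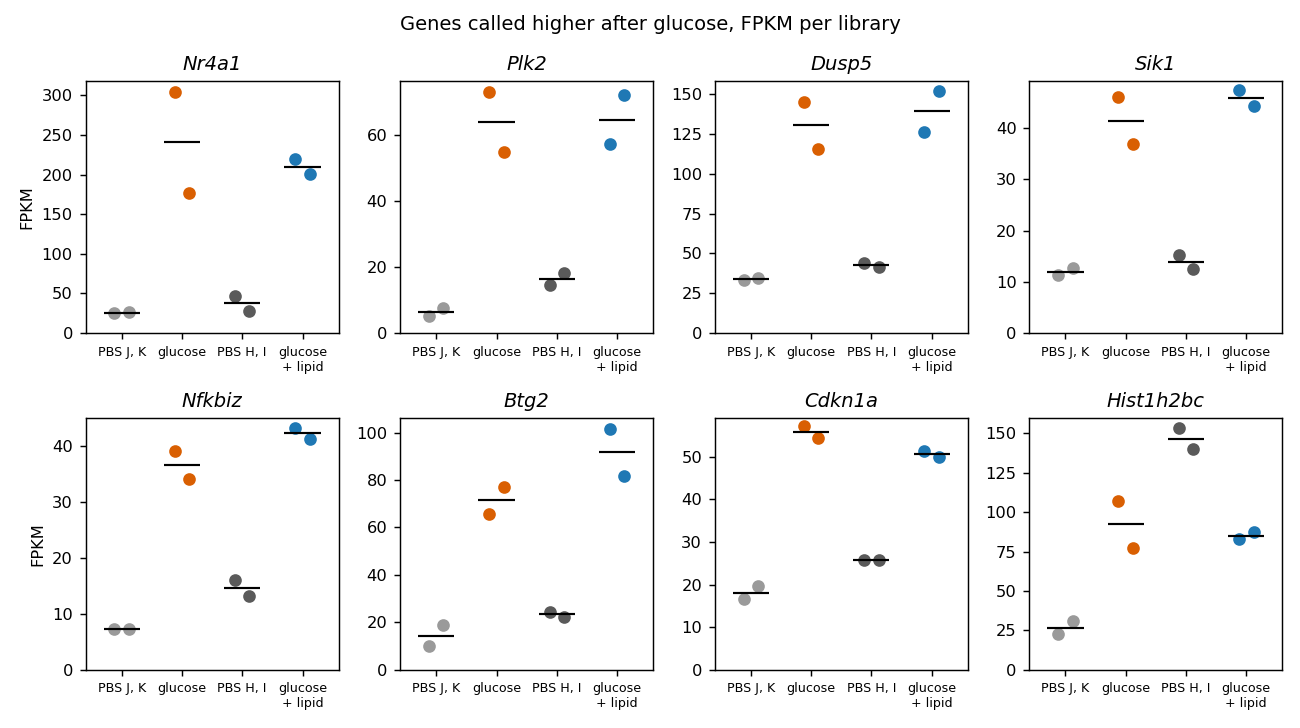
FPKM of 8 genes in each of the 8 libraries, with a line at the mean of each group of 2. Nr4a1 averaged 240.6 FPKM after glucose and 210.2 after glucose with lipid, against 25.9 in PBS J and K and 37.7 in PBS H and I, while Hist1h2bc was highest in PBS H and I.

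No gene other than a microRNA passed in the lower direction. The 8 genes named there by the rule included the haemoglobin gene Hbb-b2 (log2 fold change -5.17 ± 0.76, adjusted p = 0.0836), the mitotic checkpoint gene Trip13 (-0.81 ± 0.12, adjusted p = 0.0945) and the DNA repair nuclease genes Eme1 (-0.87 ± 0.13, adjusted p = 0.0945) and Fen1 (-0.53 ± 0.09, adjusted p = 0.119). The other 4 were Mrpl55, Rab34, Eno1 and Nans, with log2 fold changes of -0.60, -1.07, -1.97 and -0.60 and adjusted p from 0.111 to 0.12. With PBS H and I as controls Fen1, Mrpl55 and Nans had -0.11, -0.06 and -0.16, and Eno1 -0.82. The fall of Hbb-b2 was not one of beta-globin as a whole below both controls. Summed over Hbb-b1, Hbb-b2 and Beta-s, FPKM was 256.0 and 268.1 after glucose, against 540.4 and 264.1 in PBS J and K. The 2 microRNA genes that passed were each listed at 0 in 1 of the groups. Mir5107 was listed at 539.2 and 604.6 FPKM after glucose and at 0 in every PBS library, and Mir3061 at 469.2 and 465.4 FPKM in PBS J and K and at 0 in the other 6 libraries. Mir5107 (chromosome 18, 60812076 to 60812163) lies inside Cd74 on the same strand, and Cd74 itself did not pass (log2 fold change 0.47, adjusted p = 0.681).

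Among the fixed lists, immediate early genes, which also respond to the handling of cells, were higher, with a median log2 fold change of 0.84 over 28 members and an adjusted camera p of 2.17e-17 (adjusted p = 0.199 with an estimated correlation). In this list 3 members rose over all genes tested, and 21 rose and 1 fell when adjusted over the list alone. The list of p53 targets and cell cycle inhibitors had a median of 0.29 (adjusted p = 0.000945, and adjusted p = 0.26 with an estimated correlation), and the 3 of its 21 members that rose, by either adjustment, were Plk2, Cdkn1a and Btg2. Btg2 is also a member of the immediate early list, so these lists are not separate results. Trp53inp1 had a log2 fold change of 1.24 without passing, and -0.32 with crossed controls. The NF-kB and inflammatory list had a median of 0.45 (adjusted p = 1.04e-06, and adjusted p = 0.34 with an estimated correlation), with 1 of 30 members risen over all genes, Nfkbiz, and 2 when adjusted over the list alone. The chemokine genes Ccl4 and Ccl3 had log2 fold changes of 2.1 ± 0.40 and 1.73 ± 0.47 without passing (adjusted p = 0.159 and 0.226). In the interferon response list 41 of 45 members lay above 0, with a median of 0.48 (adjusted p = 1.42e-08, and adjusted p = 0.547 with an estimated correlation), none passed over all genes and 1 did when adjusted over the list alone. Its members Ifi203, Oas3 and Irf1 had log2 fold changes of 0.78 ± 0.15, 0.73 ± 0.18 and 0.66 ± 0.20. With PBS H and I as controls these were -0.14, 0.06 and 0.27, since Ifi203 stood at 53.4 FPKM in that pair, 48.4 after glucose and 27.7 in PBS J and K. The interferon and NF-kB medians were 0.18 and 0.17 without PBS replicate 3 and 0.27 and 0.16 with crossed controls, with the calls kept, and the p53 median was 0.17 with crossed controls and 0.49 without PBS replicate 4.

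Genes of long-term stem cells lay above 0 for 28 of 29 members, with a median of 0.28 (adjusted p = 9.11e-06, and adjusted p = 0.516 with an estimated correlation), with Hlf at 0.46 ± 0.16 (0.12 with crossed controls) and Egr1 at 0.68 ± 0.25 (0.36 without PBS replicate 4), neither of which passed. Genes of lymphoid-primed progenitors had a median of 0.41 (adjusted p = 0.00483, and adjusted p = 0.547 with an estimated correlation), with Flt3 at 0.57 ± 0.18. B and plasma cell markers lay above 0 for 9 of 9 members, with a median of 0.47 (adjusted p = 0.00938, and adjusted p = 0.644 with an estimated correlation). No member of these lists passed over all genes or when adjusted over the list alone. Igj, the joining chain of secreted antibodies, was listed at 23.7 and 3.95 FPKM after glucose against 0 and 0.315 in PBS J and K, and Ly6d, a lymphoid marker, at 5.28 and 2.82 against 0 and 0.309. With PBS H and I as controls their log2 fold changes of 3.27 and 2.1 became 0.80 and 0.42, those of the members Bank1 and Vpreb1 turned from 1.2 and 0.89 to -0.14 and -0.34, and the list's median was 0.57. Cd79a, a B cell receptor component, was listed at 0.109 and 0 FPKM in the glucose libraries. Without PBS replicate 3 the lymphoid-primed and B cell calls ended, at medians of 0.02 and 0.33, and the lymphoid-primed call also ended without glucose replicate 2 (0.20) and with crossed controls (0.11), where the long-term stem cell median was 0.16.

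Genes of oxidative phosphorylation were lower after glucose than in PBS J and K, with 66 of 71 below 0, a median of -0.24 and an adjusted p of 2.32e-16 (adjusted p = 0.26 with an estimated correlation). None passed over all genes and 18 fell when adjusted over the list alone, among the leading members Ndufs6 (-0.49 ± 0.09) of complex I and Uqcr11 (-0.48 ± 0.09) of complex III. Heat shock and chaperone genes lay below 0 for 25 of 25 members, with a median of -0.43 (adjusted p = 9.96e-14, and adjusted p = 0.418 with an estimated correlation). For these, 0 passed over all genes and 20 fell when adjusted over the list alone, with Hspd1 at -0.72 ± 0.13 and Hsph1 at -0.87 ± 0.20. S phase genes had a median of -0.27 (adjusted p = 6.44e-09, and adjusted p = 0.428 with an estimated correlation) and TCA cycle genes of -0.25 (adjusted p = 0.00027, and adjusted p = 0.34 with an estimated correlation). When adjusted over the list alone, 1 and 6 of them fell, against none over all genes. Glycolysis genes had a median of -0.15 and G2 and M phase genes of -0.11, both at an adjusted p of 0.033 (adjusted p = 0.658 and 0.823 with an estimated correlation). With PBS H and I as controls the medians were 0.03 for oxidative phosphorylation, -0.09 for heat shock, 0.01 for S phase, -0.02 for the TCA cycle and -0.06 for glycolysis, and none of these 5 calls held. Among the members named, Uqcr11 then turned to 0.03, and Ndufs6, Hspd1 and Hsph1 had -0.14, -0.18 and -0.26. The glycolysis call also ended without glucose replicate 2 (-0.14) or PBS replicate 3 (-0.13), and the G2 and M phase call without glucose replicate 1 (0.01) or PBS replicate 4 (0.03), while with crossed controls the latter median was -0.41.

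The test called 11 genes higher and 1 lower, with 1772 genes at an unadjusted p under 0.05. In 47.1% of genes both glucose libraries lay beyond both controls, where chance gives 33.3% if pairs of libraries do not differ otherwise. PBS H and I against PBS J and K, with no treatment between them, had 2058 genes at an unadjusted p under 0.05 in limma. The excess over 33.3% therefore cannot be laid to glucose alone. The higher count was 7 without glucose replicate 1 or PBS replicate 3, and 27 without PBS replicate 4 or either library of glucose with lipid. The lower count was 2 without glucose replicate 1 or PBS replicates 1, 2 or 4, and 5 without either library of glucose with lipid. With PBS H and I as controls 7 of the 10 genes other than microRNAs were still called, and Hist1h2bc, Btg2 (1.57) and Ppp1r15a were not. Plk2 and Nfkbiz were still called with these controls, at 1.9 and 1.27.

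The next comparison addresses glucose given together with lipid. Here, too, LSK cells held more Nr4a1, Plk2, Dusp5, Sik1 and Nfkbiz transcript than their PBS controls. Of the 7 genes called higher, 6 were also called higher after glucose alone, among them Mir5107, listed at 0 in every PBS library. Independent calls would share 0.00645 genes. Both comparisons use the same estimate of spread per gene, so the calls are not independent and that value is too low a yardstick. Nr4a1 stood at 210.2 ± 12.6 FPKM (SD, n = 2) against 37.7 ± 13.2 in PBS H and I, and Dusp5 at 139.2 ± 18.3 against 42.7 ± 1.62. Ctsw, a cathepsin of cytotoxic lymphocytes, stood at 35.8 ± 1.97 FPKM against 12.0 ± 0.901, but at 26.9 ± 2.85 in PBS J and K. Spns2, a transporter of sphingosine 1-phosphate, stood lower at 24.7 ± 2.1 FPKM against 71.4 ± 3.95. Replicate 1 of this group also held large amounts of neutrophil transcripts that replicate 2 did not.

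Nr4a1 rose by 2.49 ± 0.28 on the log2 scale (SE, adjusted p = 0.0381), Plk2 by 1.92 ± 0.22 (adjusted p = 0.0381) and Dusp5 by 1.68 ± 0.14 (adjusted p = 0.0122). Sik1 rose by 1.66 ± 0.16 and Nfkbiz by 1.47 ± 0.14, both at an adjusted p of 0.0166, and Ctsw by 1.5 ± 0.14 (adjusted p = 0.015), although with PBS J and K as controls its change was 0.40 and not called. The log2 fold change of Spns2 was -1.49 ± 0.16 (adjusted p = 0.0349), but PBS J and K held 22.01 ± 2.98 FPKM, and with these as controls it was 0.16. Ctsw lies on chromosome 19 at 5465043 to 5468507 and Spns2 on chromosome 11 at 72451638 to 72489904. Cdkn1a (0.95 ± 0.12, adjusted p = 0.0549) and the translation initiation gene Eif1 (0.66 ± 0.09, adjusted p = 0.0758) filled the remaining places without passing. In the lower direction Fgfrl1, Spred1 and Plekha3 had log2 fold changes of -1.86, -1.82 and -1.82, and Spast, Pcbp1, Smc4 and Zfp54 of -0.96, -1.07, -0.79 and -1.25, with adjusted p from 0.0758 to 0.12. With PBS J and K as controls Plekha3 turned to 0.11, Fgfrl1 and Spred1 had -0.38 and -0.23, and the other 4 -0.18, -0.20, -0.19 and -0.15. The microRNA gene Mir5107 was listed at 3431 and 944.9 FPKM, against 0 in PBS. Mir3112 was listed at 1619 and 1641 FPKM in PBS H and I and at 0 in the other 6 libraries.

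The immediate early list had a median of 0.93 (adjusted p = 1.05e-20, and adjusted p = 0.145 with an estimated correlation). In it 2 of 28 members rose over all genes, Dusp5 and Nr4a1, and 22 when adjusted over the list alone, while Btg2 (1.92 ± 0.26) and Junb (1.06 ± 0.15), a subunit of the AP-1 factor, had adjusted p of 0.0758 over all genes. The p53 and cell cycle inhibitor list had a median of 0.26 (adjusted p = 5.46e-05, and adjusted p = 0.152 with an estimated correlation), with 1 member risen over all genes, Plk2, and 3 when adjusted over the list alone. The NF-kB list had a median of 0.31 (adjusted p = 1.02e-06, and adjusted p = 0.405 with an estimated correlation), with 1 member risen over all genes and 4 when adjusted over the list alone. In the interferon list 42 of 45 members lay above 0, with a median of 0.53 (adjusted p = 3.28e-11, and adjusted p = 0.451 with an estimated correlation). None passed over all genes and 6 rose when adjusted over the list alone, with Cxcl10 at 2.31 ± 0.46 and Irgm1 at 0.64 ± 0.12. The unfolded protein response list had a median of 0.16 (adjusted p = 0.00438, and adjusted p = 0.5 with an estimated correlation), with 0 and 3 members risen by these adjustments, and Atf4, a translation stress factor, at 0.72 ± 0.10 (adjusted p = 0.0786).

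Genes of cholesterol synthesis lay above 0 for 22 of 23 members after glucose with lipid, with a median of 0.39 (adjusted p = 3.77e-09, and adjusted p = 0.405 with an estimated correlation). None passed over all genes and 6 rose when adjusted over the list alone. Insig1, a regulator of sterol sensing, had a log2 fold change of 0.92 ± 0.17 (adjusted p = 0.164 over all genes), and the synthesis enzymes Fdft1 and Sqle 0.66 ± 0.17 and 0.51 ± 0.14 (0.06 for Sqle with crossed controls). Without replicate 1 of the group the median was 0.40, and with crossed controls 0.12 with an adjusted p of 0.0354. PBS H and I differed from PBS J and K in this list by a median of -0.22. G2 and M phase genes lay below 0 for 38 of 39 members, with a median of -0.31 (adjusted p = 1.27e-08, and adjusted p = 0.48 with an estimated correlation), and Ect2, a regulator of cytokinesis, at -0.58 ± 0.11 (-0.02 with crossed controls). None passed over all genes, 1 fell when adjusted over the list alone, and with crossed controls the call ended at a median of -0.03. Heat shock genes had a median of -0.14 (adjusted p = 0.00387, and adjusted p = 0.604 with an estimated correlation) and antioxidant genes of 0.10 (adjusted p = 0.0146, and adjusted p = 0.451 with an estimated correlation), and no member of either passed by any adjustment. With crossed controls the p53, NF-kB and heat shock medians were 0.54, 0.53 and -0.54, and the unfolded protein response and antioxidant calls ended at -0.20 and 0.09, as they did without PBS replicate 1 (0.07 and 0.10). The heat shock call ended without replicate 2 of the group (-0.10) or PBS replicate 2 (-0.12).

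Markers of 6 of 7 mature cell types were higher in the comparison with lipid, those of neutrophils through replicate 1, while mast cell markers had a median of -0.47 with 7 of 10 below 0 and did not pass. In that library the neutrophil alarmin genes S100a8 and S100a9 stood at 35390 and 17287 FPKM, against at most 240.5 and 105.9 in the other 7 libraries. The granule gene Ngp stood at 4450 FPKM against at most 37.7, the lysozyme gene Lyz2 at 4622 against at most 481.3, and Cd79a at 19.1 against at most 0.38. Kit (164.1 FPKM) and Cd34 (424.1 FPKM), which mark stem and progenitor cells, were lowest of the 8 libraries there. For Kit the margin was small, with 165.7 FPKM in PBS replicate 3. Ly6a was not lowest, at 319.0 FPKM against 295.4 and 299.1 in PBS replicates 1 and 3. The medians were 3.58 for neutrophil, 1.84 for B cell, 1.43 for erythroblast, 1.42 for monocyte, 0.61 for dendritic cell and 0.41 for T and NK cell markers. Granulocyte-monocyte and megakaryocyte-erythroid progenitor genes had medians of 0.56 and 0.63. All 8 lists passed camera, with adjusted p from 6.92e-06 to 0.0133, and none held with an estimated correlation (adjusted p = 0.408 to 0.643). Without replicate 1 the neutrophil median was 0.08, that of erythroblasts 0.41, of monocytes 0.22, of T and NK cells 0.08 and of the progenitor lists -0.24 and 0.18, and these 6 calls ended, as did those of the antioxidant (0.08) and unfolded protein response (-0.03) lists. The B cell and dendritic cell calls held at 0.63 and 0.67. Hba-a1 stood higher in replicate 2 (667.8 FPKM) than in replicate 1 (373.6 FPKM). Its near-identical copy Hba-a2 went the other way, at 18.9 FPKM in replicate 2 and 751.7 in replicate 1. The sum of these copies was 686.7 FPKM in replicate 2 and 1125 in replicate 1. The granulocyte-monocyte call also ended without PBS replicate 2 (0.34) and the T and NK cell call with crossed controls (0.30).

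**Figure D2:**
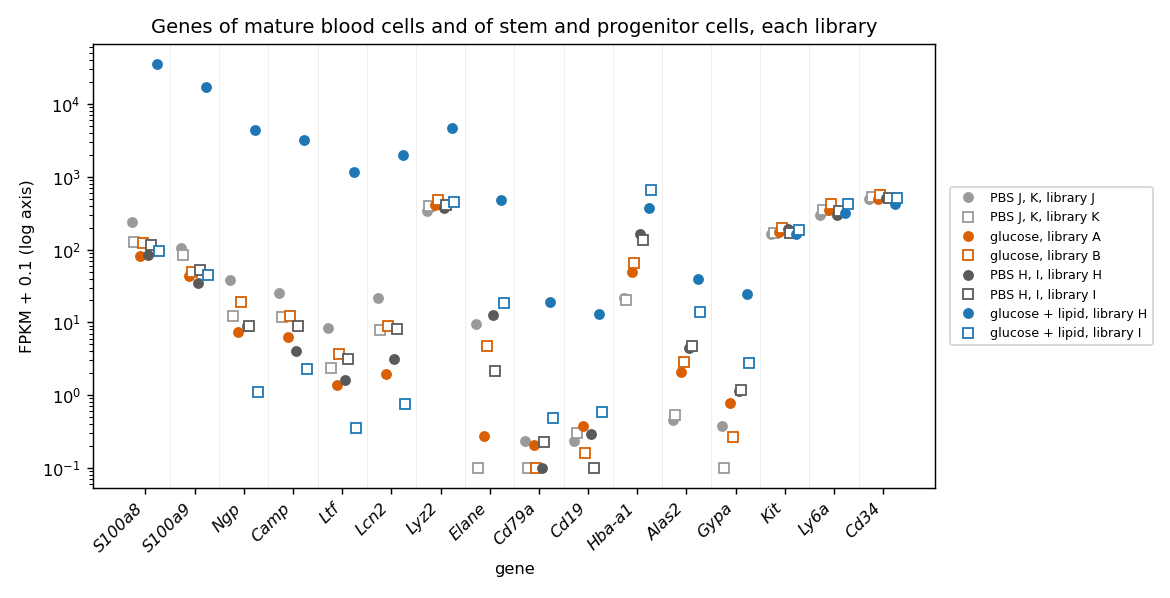
FPKM, with 0.1 added and on a log axis, of 16 genes in each of the 8 libraries. Replicate 1 of glucose with lipid held 35390 FPKM of S100a8, against 81.8 to 240.5 in the other libraries.

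The test called 7 genes higher and 2 lower, with 1407 at an unadjusted p under 0.05. In 44.0% of genes both treated libraries lay beyond both controls, where chance gives 33.3% if pairs of libraries do not differ otherwise. Since the PBS pairs did differ, this excess cannot be laid to treatment alone. The higher count was 1 without PBS replicate 1, 2 without PBS replicate 2, 4 without replicate 1 of the group and 16 without PBS replicate 3 or 4. Without replicate 2 of the group, which leaves the library with mature-cell transcripts, 254 genes were higher and 17 lower. Without replicate 1, 7 of the 7 called genes other than microRNAs kept their direction and 1, Dusp5, was still called, and with PBS J and K as controls 5 were still called, among them Plk2 at 3.14 and Nfkbiz at 2.38. Cdkn1a was then called at 1.44. With no filter on low values, 7 of these 7 kept their direction and 0 were still called. The same held with only the 4 libraries of the comparison.

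All 4 glucose-injected libraries were then set against all 4 PBS libraries with the control set as a block, a comparison chosen after the values were seen. The treated cells held more Nr4a1, Atf3, Fos and Junb transcript: 32 genes rose and none fell in limma, with 1360 at an unadjusted p under 0.05 in either direction. Atf3 rose by 2.93 ± 0.31 (adjusted p = 0.00731), Nr4a1 by 2.80 ± 0.22 (adjusted p = 0.00146), Fos by 1.38 ± 0.16 (adjusted p = 0.0115) and Junb by 0.96 ± 0.11 (adjusted p = 0.0103). Klf2 and Klf6, zinc finger factors, rose by 1.5 ± 0.20 and 1.30 ± 0.15, and the NF-kB inhibitor Nfkbid by 1.04 ± 0.11. The negative regulators Zfp36, which promotes mRNA decay, and Dusp1, a MAP kinase phosphatase, rose by 1.03 ± 0.12 and 0.88 ± 0.13, and Atf4 by 0.62 ± 0.08 (adjusted p = 0.0246). Hba-a1 and Beta-s, which encode haemoglobin chains, rose by 1.57 ± 0.19 and 1.61 ± 0.22, and both also differed between the PBS pairs. Atf3, Fos, Klf2, Nfkbid, Zfp36, Dusp1 and Beta-s fell outside the naming rule and were chosen after their values were seen.

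Markers of 6 of 7 mature cell types were higher in this fit too, while mast cell markers had a median of -0.37 with 7 of 10 below 0 and did not pass (camera adjusted p = 0.167). B and plasma cell markers had a median of 0.95, with 0 of 9 members risen over all genes and 8 when adjusted over the list alone (camera adjusted p = 1.02e-06). The medians were 1.46 for neutrophil, 1 for erythroblast, 0.78 for monocyte, 0.36 for dendritic cell and 0.35 for T and NK cell markers (camera adjusted p from 0.000416 to 0.0329), and none of these 6 lists held with an estimated correlation (adjusted p = 0.275 to 0.601). Without replicate 1 of glucose with lipid the neutrophil, monocyte and T and NK cell calls ended at -0.47, 0.14 and 0.09, those of B cells, erythroblasts and dendritic cells held at 0.67, 0.22 and 0.38, and the immediate early median was 0.89.

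In the immediate early list 12 of 28 members rose over all genes, and 24 rose and 1 fell when adjusted over the list alone, and the list held with an estimated correlation (adjusted p = 0.0146), but not without replicate 1 of glucose with lipid (adjusted p = 0.0607), PBS replicate 1 (0.0673) or PBS replicate 2 (0.0576). The list score, the mean of the members' log2 values each centred on its mean, was 0.50 ± 0.13 (SD, n = 4) in treated and -0.50 ± 0.12 in PBS libraries. The lowest treated score was 0.33 and the highest PBS score -0.41, with a 2-sided exact permutation p of 0.0286, the smallest that 70 arrangements allow, and 0.0556, again the smallest possible, over the 36 arrangements within control sets. The p53 and cell cycle inhibitor list also held (median 0.33, adjusted p = 0.0462 with an estimated correlation), though not on leaving out any 1 of the 8 libraries (adjusted p = 0.0666 to 0.191), while the interferon list, with 22 of 45 members risen when adjusted over the list alone and none over all genes, did not (median 0.52, adjusted p = 0.275 with an estimated correlation). The genes known to be raised with age in stem cells had a median of 0.20 (camera adjusted p = 0.0153, and adjusted p = 0.262 with an estimated correlation), and of 0.08 without PBS replicate 1 (camera adjusted p = 0.0387). For that list the treatments taken singly gave medians of 0.11 and 0.12 (camera adjusted p = 0.127 and 0.0654). The treated libraries all lay on 1 side of the PBS libraries for 6.39% of genes. Chance gives 2.86% if all 8 libraries are exchangeable, an assumption that the differing control sets do not meet. The count of 32 was 8 without glucose replicate 2, 13 without PBS replicate 1 and 17 without PBS replicate 2, and the lower count was 1 without replicate 2 of glucose with lipid or PBS replicate 2 and 3 without PBS replicate 4.

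**Figure D3:**
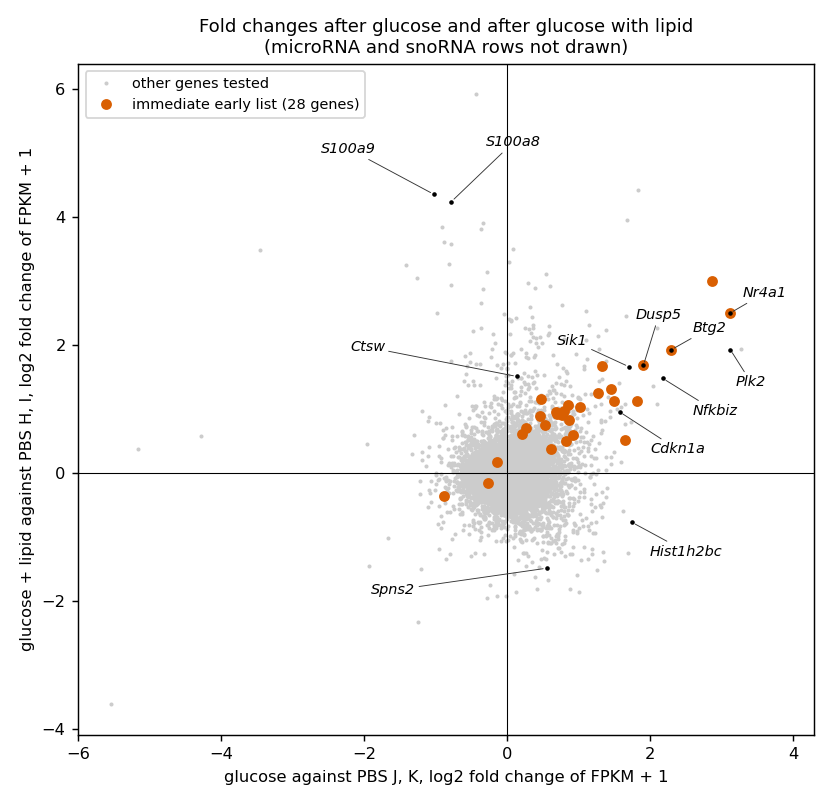
Log2 fold change of each tested gene after glucose (horizontal) and after glucose with lipid (vertical), each against its PBS controls, with immediate early genes in orange and microRNA and small nucleolar RNA genes not drawn. Across all genes Pearson's r was 0.08, while the immediate early list had medians of 0.84 and 0.93.

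Genes chosen for the study's subject, metabolism and stem cell identity, did not pass in either treatment apart from Cdkn1a after glucose. Ranges here are over crossed controls and the leaving out of each library. Txnip, a glucose-induced inhibitor of thioredoxin, had log2 fold changes of 0.11 ± 0.21 after glucose (range -0.31 to 0.29) and 0.04 ± 0.21 after glucose with lipid (-0.20 to 0.46). The pyruvate dehydrogenase kinase gene Pdk1 had 0.24 ± 0.14 (-0.01 to 0.34) and -0.22 ± 0.14 (-0.36 to 0.03), and Pdk2 0.87 ± 0.26 (0.31 to 1.24, adjusted p = 0.237) and 0.14 ± 0.26 (-0.02 to 0.70). Cpt1a, which admits fatty acids to mitochondria, had -0.02 ± 0.13 (-0.17 to 0.14) and -0.14 ± 0.13 (-0.16 to -0.12). After glucose Kit had 0.15 (0.04 to 0.24), Ly6a 0.25 (0.13 to 0.38) and Cd34 0.03 (-0.07 to 0.14), and the stem cell markers Slamf1 and Procr had 0.24 (-0.07 to 0.55) and 0.50 (0.46 to 0.58). With lipid these had -0.04 (-0.14 to 0.07), 0.22 (0.01 to 0.42), -0.15 (-0.28 to -0.02), 0.24 (0.10 to 0.38) and 0.49 (0.15 to 0.82). After glucose Mpo had -0.01 (-0.48 to 0.47), Cebpa -0.31 (-0.79 to 0.17), Gata1 -0.15 (-0.20 to 0.31), Ikzf1 0.08 (-0.19 to 0.15), Klf5 0.38 (-0.30 to 1.07) and the proliferation marker Mki67 -0.11 (-0.38 to 0.09). With lipid these had 0.80 (-0.47 to 2.07), 0.09 (-0.07 to 0.25), 1.68 (0.42 to 2.95), -0.10 (-0.21 to 0.17), 1.1 (0.62 to 1.58) and -0.27 (-0.47 to 0.00). Replicate 1 of glucose with lipid held 649.5 FPKM of Mpo against 110.9 in replicate 2, and the lowest values of Mpo, Gata1 and Klf5 with lipid were those without it. Pdk4, Il7r and Cdkn2a were below the level tested, and Cdkn2a was listed at 0 in all 8 libraries. The list of pyruvate dehydrogenase and its kinases had medians of -0.07 and -0.14 and means of 0.01 and -0.11 (camera adjusted p = 0.889 and 0.0599), and that of fatty acid oxidation -0.01 and 0.02 (camera adjusted p = 0.61 and 0.533).

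The difference between the effects of glucose with lipid and of glucose addresses what lipid adds. No gene other than Mir3061 and Mir3112 passed, with 1456 genes at an unadjusted p under 0.05 in limma. Ctsw (difference in log2 fold change 1.37 ± 0.19, adjusted p = 0.173) led the genes higher with lipid, followed by Zdhhc23, Mrpl52, Fdx1l and Tmem120a at 1.71, 0.66, 0.94 and 1.13 (adjusted p = 0.238). Hist1h2bc (-2.53 ± 0.27, adjusted p = 0.0638) and Spns2 (-2.05 ± 0.23, adjusted p = 0.0765) led those lower with lipid, followed by Fgfrl1, Plekha3 and Rock2 at -2.87, -2.70 and -1.39 (adjusted p = 0.113, 0.173 and 0.204). For most of these genes the difference lay largely between the controls. Ctsw stood at 29.6 FPKM after glucose and 35.8 with lipid, against 26.9 in PBS J and K and 12.0 in PBS H and I. Hist1h2bc stood at 92.5 and 85.1 against 26.8 and 146.8. With pooled controls, which sets the treated groups against each other, Fgfrl1 and Tmem120a still differed by -1.39 and 0.54, and the others by -0.78 to 0.30. With the controls crossed 10 of these 10 genes turned direction, Ctsw to -0.83, Hist1h2bc to 2.33, Spns2 to 1.27 and Plekha3 to 1.15. Fgfrl1 and Tmem120a turned only to 0.09 and -0.05. For the immediate early list the median difference was 0.11 (camera adjusted p = 0.879). For Nr4a1 and Plk2 the differences were -0.62 ± 0.40 and -1.20 ± 0.31, neither of which passed (adjusted p = 0.556 and 0.301). Across 11931 genes, which are not independent replicates, the fold changes of the treatments had a Pearson correlation of 0.08 and a Spearman correlation of 0.06, and simulated data without effects gave a Pearson correlation of -0.01. The count of 2 was 141 without replicate 2 of glucose with lipid, 6 without glucose replicate 2, 5 without PBS replicate 1 or 4 and 4 without PBS replicate 2 or 3.

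PBS H and I against PBS J and K shows how far untreated controls differed. Transcripts of the haemoglobin genes Beta-s and Hba-a1 were higher in PBS H and I: Beta-s differed by 3.01 ± 0.28 on the log2 scale (SE, adjusted p = 0.0173) and Hba-a1 by 2.77 ± 0.26 (adjusted p = 0.0173). Hbb-b1 stood at 299.5 and 288.1 FPKM there, between the 406.1 and 205.9 FPKM of PBS J and K. Hist1h2bc was higher by 2.43 ± 0.19 (adjusted p = 0.00679) and Spns2 by 1.66 ± 0.16 (adjusted p = 0.0192), and with Mir3112 higher and Mir3061 lower there were 6 calls, with 2058 genes at an unadjusted p under 0.05. Lists of oxidative phosphorylation (median -0.27, adjusted p = 9.77e-16), heat shock (-0.39, adjusted p = 2.94e-10), ribosomal protein (-0.27, adjusted p = 2.85e-09), S phase (-0.24, adjusted p = 2.62e-08), unfolded protein response (-0.42, adjusted p = 0.000355), cholesterol synthesis (-0.22, adjusted p = 0.00106) and TCA cycle genes (-0.19, adjusted p = 0.00326) were lower in PBS H and I. Mast cell markers (1.22, adjusted p = 0.00019), G2 and M phase genes (0.27, adjusted p = 9.73e-05), NF-kB and inflammatory genes (0.19, adjusted p = 0.0152), erythroblast markers (0.58, adjusted p = 0.0219) and autophagy and lysosome genes (0.08, adjusted p = 0.0463) were higher. None of these 12 lists held with an estimated correlation (adjusted p = 0.489 to 0.646). Oxidative phosphorylation, heat shock, S phase and TCA cycle genes were also lower after glucose than in PBS J and K. Cholesterol synthesis and unfolded protein response genes were higher after glucose with lipid than in PBS H and I. The count of 6 was 14 and 15 without replicates 1 and 2 of glucose with lipid, and 3 without PBS replicate 2.

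**Figure D4:**
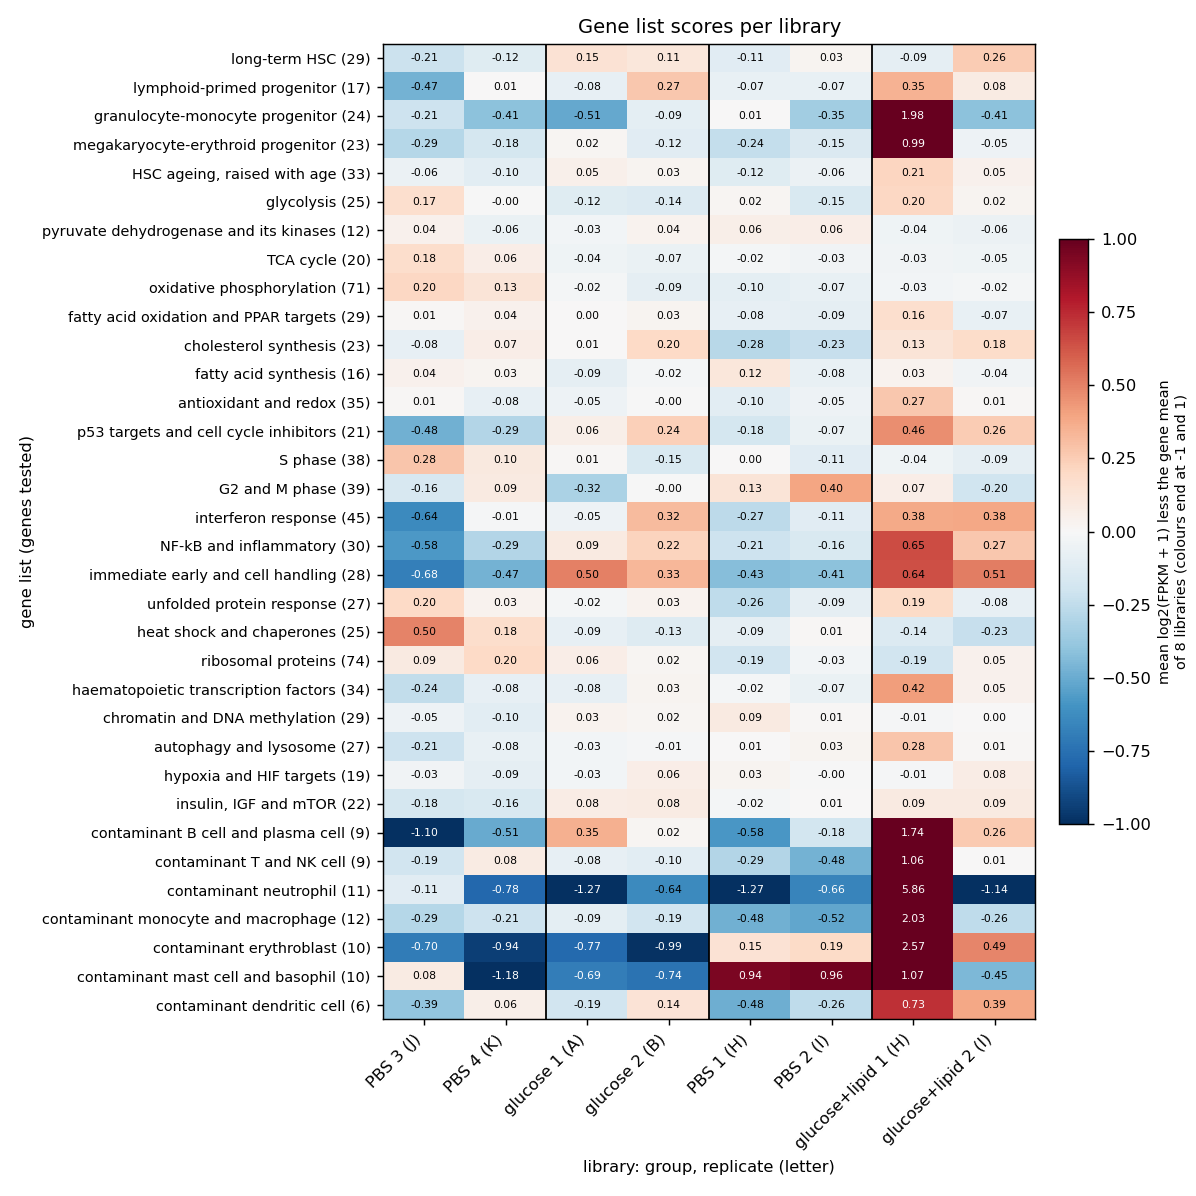
Scores of 34 gene lists in the 8 libraries, each the mean of its members' centred log2 values, drawn as colours. The neutrophil score of replicate 1 of glucose with lipid was 5.86, against at most -0.11 in the other libraries, and the immediate early scores ran from 0.33 to 0.64 in treated and from -0.68 to -0.41 in PBS libraries.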

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

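The explanations weighed here were tested only after the result was seen, while the searches for stray control values and for differences between treatments had been set beforehand. Among 181 values examined in the 4 PBS libraries, 9 had 1 library standing apart, against 9.05 expected by chance at a rate of 1 in 20. As the share of the range taken by the gap to the nearest library, these were Tal1 at 0.867 and Klrd1 at 0.835 in PBS replicate 4, and Bcl11a at 0.842, Irf1 at 0.911, Klf6 at 0.842, Cct4 at 0.835 and Cd2 at 1 in PBS replicate 3. The lymphoid-primed list score stood apart at 0.834 in PBS replicate 3, and the score of pyruvate dehydrogenase and its kinases at 0.840 in PBS replicate 4. The values are correlated, so a count near the expected one does not show that no control library stands apart. On the second principal component of the log2 values (18.2% of the variance), PBS replicate 3 stood at 39.4. The next highest library, replicate 1 of glucose with lipid, stood at 15.5. PBS replicate 3 is a control of glucose.

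The difference of effects, glucose with lipid less glucose, passed camera for 15 lists, of which 0 held with an estimated correlation (adjusted p = 0.638 to 0.811). The median differences on the log2 scale were -0.16 for long-term stem cell and -0.16 for G2 and M phase genes, 0.32 for glycolysis, 0.17 for the TCA cycle, 0.27 for oxidative phosphorylation and 0.27 for cholesterol synthesis. They were 0.24 for antioxidant, 0.26 for S phase, 0.39 for unfolded protein response, 0.30 for heat shock and 0.17 for ribosomal protein genes. Among mature-cell markers they were 0.64 for T and NK cells, 4.36 for neutrophils, 1.47 for monocytes and macrophages and 1.04 for erythroblasts. Without replicate 1 of glucose with lipid 9 of the 15 lists were still called in the same direction, and the long-term stem cell median was 0.02, that list having 0.30 with lipid (camera adjusted p = 7.19e-05) in place of 0.12. With crossed controls 2 were, those of neutrophils and erythroblasts, and 9 turned direction. Without replicate 1 of glucose with lipid, the neutrophil and erythroblast median differences were 0.41 and 0.27, and that of monocytes and macrophages was -0.01. Mir3061 and Mir3112 differed at adjusted p of 4.59e-06 and 1.05e-06, each being listed at 0 outside 1 pair of PBS libraries.

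Neutrophil transcripts of glucose with lipid stood in replicate 1, while the B cell and dendritic cell calls held without it. For neutrophil genes the score of replicate 2 was -1.14, between those of PBS replicates 1 and 2 (-1.27 and -0.66). It differed from the higher of these controls by -0.47. A response of the sorted cells shared by both libraries, as large as in replicate 1 (5.86), is thus argued against. A smaller shared response stays undecided, since a score within the range of 2 controls cannot exclude it. Single genes went both ways. Retnlg stood at 14.1 FPKM in replicate 2 against 0 and 3.95 in these controls, and Camp at 2.18 against 3.99 and 8.82. For the other 6 mature blood lists a shared response stays open, as replicate 2 lay above both of its controls for 5 of them. Mature marrow cells carried through the sort are a candidate explanation, although the Lineage- gate should remove such cells. This library was the highest of 8 for 7 of the 7 mature blood lists, with S100a8 at 35390 FPKM and Cd79a at 19.1 FPKM. For mast cells its lead was small (score 1.07 against at most 0.96). Being highest was not particular to these lists. It also held for antioxidant (0.27 against at most 0.01) and glycolysis genes (0.20 against at most 0.17), among others, though not for oxidative phosphorylation or S phase genes. A response in the animal or animals behind this library alone stays open, since the labels do not say whether a library came from 1 mouse or a pool, as does free RNA from lysed cells.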

How the results depend on the processing

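The removal of microRNA and small nucleolar RNA values, library weights, pooled controls with replicate 2 alone of glucose with lipid, and the tests of all treated against all PBS libraries were chosen only after the data were seen. Over 176 values of named genes and 22 settings, 3568 kept their direction and side of the threshold, 92 lost and 92 gained a call, and 3 turned, while a further 86, called neither before nor after, changed sign, 33 of them with crossed controls and 16 with the replicate block. Of the called values, Hist1h2bc after glucose turned to -0.68 with crossed controls and -0.68 with the replicate block. That block leaves PBS replicates 3 and 4 alone, so it also makes PBS replicates 1 and 2 the controls of glucose, and its values there cannot be laid to the block alone. Spns2 after glucose with lipid turned to 0.16 with crossed controls, where the other PBS pair differed in level. For the other changes the cause was not tested. Depth is known only by estimate, and with 2 libraries a group, log2 changes near 1 were often missed in simulated data. Differences between replicates 1 and 2 correlated at -0.04, 0.07 and -0.06 between groups, which gave no sign that equal numbers mark pairs. The largest shift of the median of all genes under another scaling was -0.03. Library weights were equal within each group, so that they could not single out a library.

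For genes higher after glucose (11), the count was 18 with a pseudocount of 0.1, 17 with a filter at 5 FPKM, 17 with quantile normalisation, 7 without trend, 6 with pooled controls, 6 with the replicate block, 18 with microRNA and small nucleolar RNA removed, 6 with pooled controls and replicate 2 alone, and 7 to 27 on leaving out 1 library. For genes lower after glucose (1), it was 3 with the 4 libraries of the comparison, 3 with the block, 2 with pooled controls and replicate 2 alone, and 1 to 5 on leaving out 1 library. For genes higher after glucose with lipid (7), it was 1 without filter, 3 with the 4 libraries of the comparison, 27 with crossed controls, 12 with those RNAs removed, 2 with pooled controls and replicate 2 alone, and 1 to 254 on leaving out 1 library. For genes lower (2), it was 1, 1, 1 and 1 with the 4 libraries, crossed controls, the block, and pooled controls with replicate 2 alone, 0 with pooled controls in limma (1207 at an unadjusted p under 0.05), 4 with those RNAs removed, and 2 to 17 on leaving out 1 library.

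For the difference of effects (2), the count was 0 with pooled controls (480 at an unadjusted p under 0.05 in limma), 0 with those RNAs removed (1482), 5 with crossed controls, 1 with the block, 1 with pooled controls and replicate 2 alone, and 2 to 141 on leaving out 1 library. Between the PBS sets (6), it was 2 without filter, 17 with the 4 PBS libraries alone, and 3 to 15 on leaving out 1 library. For all treated against all PBS libraries (32 and 0), it was 16 and 1 without filter, 19 and 1 without trend, and 8 to 32 and 0 to 3 on leaving out 1 library. Of 13, 17 and 15 lists called by camera for glucose, glucose with lipid and their difference, 0, 0 and 0 held with an estimated correlation and fry called 4, 1 and 1, while leaving out 1 library gave 11 to 16, 12 to 20 and 10 to 15. The correlation of fold changes (0.08) was 0.42 with pooled controls, where simulated data without effects gave 0.32 because the controls are shared, and 0.01 to 0.13 on leaving out 1 library.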

Other observations

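Of the tests of explanations in this part, the count over other splits had been set before its result was seen, and the others were chosen only after.

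Other lists did not pass camera in either treatment. After glucose and after glucose with lipid, haematopoietic transcription factors had medians of 0.09 and 0.10 (camera adjusted p = 0.0776 and 0.0505), and autophagy and lysosome genes of 0.05 and 0.09 (camera adjusted p = 0.0713 and 0.1). Genes of insulin, IGF and mTOR signalling had medians of 0.18 and -0.03 and means of 0.25 and 0.10 (camera adjusted p = 0.0713 and 0.817), with 3 of 22 members risen and 1 fallen after glucose when adjusted over the list alone and none over all genes. In fry, which does not compare a list with other genes, this list was higher after glucose (adjusted p = 0.0047), lower in the difference of effects (0.0465) and higher in PBS H and I than in PBS J and K (0.00514). Hypoxia genes had 0.02 and 0.04, the latter against a lower direction in camera, chromatin genes 0.12 and -0.02, fatty acid synthesis genes -0.06 and -0.04 and ribosomal protein genes -0.05 and 0.09, none of which passed. Mast cell markers had -0.26 and -0.47 (camera adjusted p = 0.889 and 0.0617), and without replicate 1 of glucose with lipid the latter became -1.58 (adjusted p = 0.00013). With crossed controls these markers had -1.64 and 0.77 (camera adjusted p = 1.92e-06 and 0.0212), and after glucose 0.43 without PBS replicate 3. Endothelial and stroma markers, untested for want of members, were highest in replicates 2 and 1 of glucose with lipid, with scores of 0.28 and 0.53.

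For the rise of immediate early genes after both treatments, the real arrangement called 32 genes and the highest of the other 33 splits of the 8 libraries 9, with 1 of 34 giving as many; since the control sets differ, splits that mix them are not exchangeable with the real one, and the 18 within sets are too few for a share under 0.05. Neutrophils in the glucose libraries are argued against by a neutrophil median of -0.78 there (0.04 with crossed controls). By estimate, 3 of 4 treated libraries were deeper than every PBS library. The 1234 genes of like level outside the list had a median of -0.00146 ± 0.355 (SD), against 0.84 for the list. FPKM is scaled by library size, so a median near 0 was likely at any depth and does not decide by itself. However, 24 of 28 list members lay above 90% of those genes, which argues against a depth effect that acts through level alone. B or plasma cells stay open, since their markers had a median of 0.47 after glucose with 9 of 9 above 0, while Cd79a was listed at 0.109 and 0 FPKM. Longer or rougher handling of the treated mice's cells cannot be told apart from the treatment, since handling times are not in the labels, and the heat shock median of -0.30 in treated against PBS libraries decides neither way. A hypothesis that remains is that repeated glucose raises these genes in LSK cells, which could be tested with handling times balanced across treatments.

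Alpha-globin and Beta-s transcripts followed the control sets, while Hbb-b1 did not. Movement of reads between the near-identical alpha-globin copies is argued against, since their sum was 7.55 times as high in PBS H and I (213.1 and 218.0 FPKM) as in PBS J and K (28.7 and 28.4 FPKM). For beta-globin the sum differed by 1.42 times. It was 586.1 and 557.2 FPKM in PBS H and I, and 540.4 and 264.1 FPKM in PBS J and K. Beta-s stood at 201.0 and 166.3 against 24.4 and 19.4 FPKM. Movement between copies stays undecided for Beta-s, since PBS replicate 3 lay near PBS H and I in this sum and PBS replicate 4 well below. Hbb-b2 overlapped between the PBS pairs (85.6 and 102.8 against 109.9 and 38.9 FPKM). After glucose it was listed at 2.31 and 0.0321 FPKM, while the beta-globin sum was 256.0 and 268.1 FPKM. That sum was near PBS replicate 4 and below PBS replicate 3, so movement between copies stays undecided for the low Hbb-b2 values too. A day or batch shared within each set may underlie the alpha-globin difference: Alas2, a single-copy gene of haem synthesis, was higher in all 4 libraries of the H and I set than in the other 4 (2-sided exact permutation p = 0.0286, the smallest possible). The labels give no dates, and the sets also differ in treatment, so a biological difference stays open and untested.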
